A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

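The source was 24 one-colour Affymetrix S98 expression arrays of yeast strain BY4730, 11 from control cells, 3 each after bleomycin, MMS and NaCl, and 2 each after cisplatin and ethanol. Per the labels' protocols, cells were exposed for 120 min, total RNA was isolated with hot phenol, poly(A)+ RNA was taken from it, and biotin-labelled cRNA was made by in vitro transcription from cDNA primed with an oligo(dT) primer carrying a T7 promoter. The deposited values were signal intensities on the log2 scale, as their range of 1.42 to 14 shows. The summary and normalization behind them are not given in the sources used here. Scanner files were not used here. The number of arrays limits the precision, and no count or depth underlies these values.

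Each array's group, replicate and day came from its label. The titles' dates place the control arrays on 11 days and tie 12 of the 13 treated arrays to a control array of the same day, so day was a fixed block in the main fit. The title of ethanol replicate 1 gives the day and month of control replicate 6 with another year, and the same day was assumed. Control replicate 8 shares its day with no treated array. Whether arrays of a day deviate together was checked on 13 pairs of a treated and a control array. The correlation of their deviations from the group means lay above 0.1 in 6 pairs and below -0.1 in 5, from -0.565 to 0.68, so the pairing rests on the labels and not on this check. The controls of the 5 agents were not treated alike per the labels, DMSO for some and medium for others, and the control arrays are not told apart there. Control arrays correlated with each other at 0.732 to 0.9965, and 0 columns were identical.

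The table held 9335 probe sets, 60 of them controls. Of the other 9275, the given probe table paired 6504 with 1 gene and 328 with several, and 2443 were not in it, so these are unnamed here. All 6504 symbols were updated through the given gene table by gene ID. The probe set with the highest mean signal stood for each of 5656 genes. Genes with a mean signal above the pooled 20th percentile (3.786 on the log2 scale) were tested, 5171 in all. 1 of the genes to be named whatever its value had no usable probe set, and STL1 and CLB2 lay below the filter, so they are not reported, and the other 19 were tested.

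Values were quantile-normalized between arrays with R 4.3.3 and limma 3.58.1. limma's lmFit was run once on all 24 arrays with 5 agent terms and the day block, which left 8 residual degrees of freedom, and eBayes with an intensity trend gave a prior of 3.8. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Contrasts of this fit gave each agent against control, the mean of the 3 DNA-damaging agents minus the mean of NaCl and ethanol, and 4 differences between agents. limma's camera tested 35 gene lists with at least 3 tested members at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. Fold changes of pairs of agents were set beside 100 simulations of unchanged groups with the same controls and days. The class fit was given 100 simulations of its own, added after the results were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

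The design, the gene lists, the filter, the threshold and most alternatives were chosen before the data were examined. Named genes followed a rule set then. For each agent they were the 6 largest rises and the 6 largest falls among called genes with the same sign on every day, up to 3 such members of each list described, and a preset group of genes. Between agents they were the 6 largest differences each way. Genes shared by the 3 damaging agents, a few further list members, and the small nucleolar RNA group were added after their values were seen.

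Alternatives changed 1 choice at a time. They were median scaling in place of quantile normalization, a pseudocount at the pooled 10th percentile (3.072 on the log2 scale) added on the linear scale, no filter, a filter at the 40th percentile (4.885), no day block, day as a random block (correlation 0.0413), the ethanol array with another year in its title as its own day, eBayes without a trend, only the arrays compared, all probe sets that are not controls, a minimum of 2-fold, and each array left out in turn. The ACT1 5′ class and its limit of 7.5, which lies in a gap of the values, were chosen after seeing the data, as was leaving aside the 3 arrays with an ACT1 3′ signal under 10. Fits with the class as a block and fits within each class came from that choice. Control probe sets over 1 log2 unit above the highest control array were listed separately.

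The procedure was tested on simulated data made from the real arrays' means and spread for 5171 genes, with 67, 67 and 66 genes changed by 1, 2 and 3 on the log2 scale. It recovered 37.3%, 86.6% and 98.5% of them for bleomycin, 28.4%, 88.1% and 98.5% for MMS, 32.8%, 92.5% and 95.5% for NaCl, 13.4%, 68.7% and 98.5% for cisplatin, and 16.4%, 76.1% and 97% for ethanol. Between 2 and 9 unchanged genes were called. camera recovered the shifted list in each of the 5 simulations and called 0 of 20 unchanged lists. The simulated errors were independent between genes and arrays. The false calls counted here therefore do not carry over to correlated genes or to arrays that share a state. A change of 1 was therefore mostly below what the fit detects, above all with 2 arrays.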

Results

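Transcript levels were measured in the budding yeast strain BY4730, a haploid laboratory strain, on 24 one-colour Affymetrix S98 arrays. Cells were exposed to 1 of 5 agents for 120 min, and 11 arrays came from control cells that received the DMSO solvent or stayed in medium. Which of these treatments each control array received is not given in the labels. 3 arrays followed bleomycin, which breaks DNA strands, 3 followed methyl methanesulfonate (MMS), which methylates DNA bases, and 2 followed cisplatin, which crosslinks them. 3 arrays followed NaCl and 2 followed ethanol, a pair of stresses that do not act on DNA directly. The titles give bleomycin at 0.15 U/ml (replicates 1 and 3) and 0.1 U/ml (replicate 2), and MMS at 0.12% (replicates 1 and 2) and 0.14% (replicate 3). They give NaCl at 10%, 8% and 9%, ethanol at 15%, and cisplatin at 500 and 650 ug without a volume. The protocol text gives other doses, 600 mg/mL for cisplatin and 10 mg/mL for NaCl, so the doses are uncertain. The control arrays fell on 11 days, and each treated array was compared with the control array of its day. For ethanol replicate 1, whose title gives another year, this is assumed. Control replicate 8 had no treated array on its day.

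The median deposited signal of an array lay between 5.33 and 5.63 on the log2 scale. The arrays differed in the signal of control probe sets at both ends of the actin transcript ACT1, taken here as a sign of the state of their RNA. The level of ACT1 itself was not told apart from that state. The ACT1 5′ signal ran from 4.76 to 10.65 in the control arrays, from 8.35 to 8.83 with MMS, from 6.03 to 6.23 with NaCl and from 4.53 to 4.67 with ethanol. With bleomycin it ran from 6.19 to 9.42 and with cisplatin from 5.18 to 9.33. The 3 MMS arrays averaged 8.65 ± 0.255 (SD), and their same-day controls 5.28 ± 0.6, so the 5′ signal differed by 3.37 within those days. For NaCl replicates 1, 2 and 3 the difference from the same-day control was 0.87, -3.93 and -3.29 (mean -2.12), and for cisplatin replicates 1 and 2 it was -5.38 and -0.13 (mean -2.76). It was -1.19 and -0.71 for ethanol (mean -0.95) and 0.95, -0.53 and -0.45 for bleomycin (mean -0.01). A low ACT1 5′ class was set at signals under 7.5, and a fit with this class in place of the day is called the class fit. 3 arrays also had an ACT1 3′ signal under 10, namely NaCl replicates 2 (7.98) and 3 (8.21) and control replicate 11 (9.37), and they are called the low-3′ arrays. The median correlation of NaCl replicates 2 and 3 with the control arrays was 0.674 and 0.656, that of control replicate 11 was 0.809, and that of every other array was at least 0.888.

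**Figure D1:**
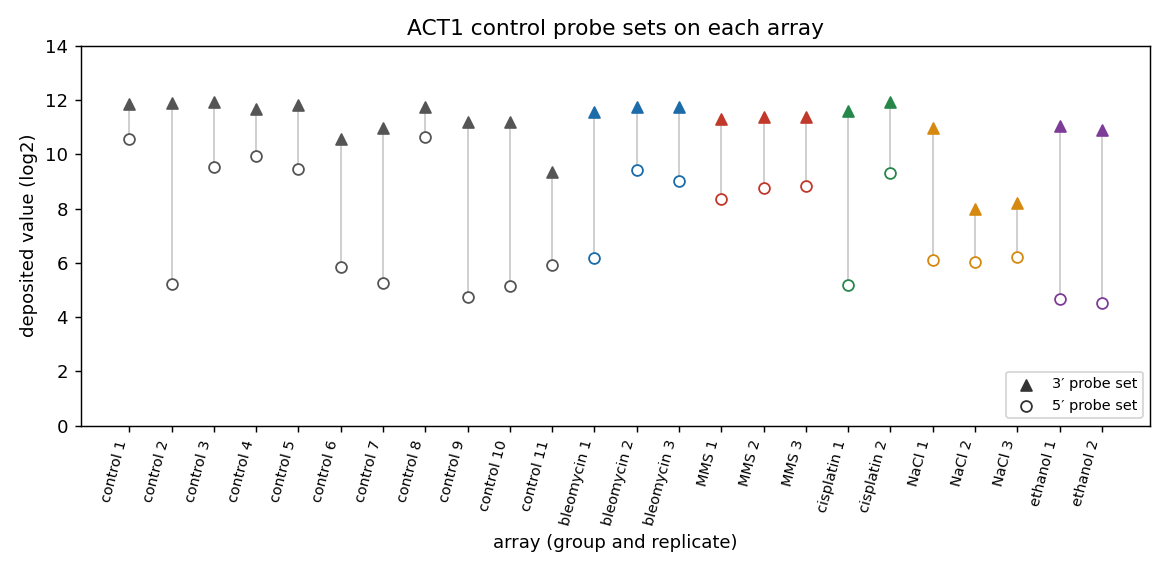
ACT1 signal of each array (deposited log2 values; triangles, 3′ probe set; open circles, 5′ probe set; a grey line joins both probe sets of an array). The 3 MMS arrays sit between 8.35 and 8.83 in the 5′ signal, and the low-3′ arrays are NaCl replicates 2 and 3 and control replicate 11.

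The strain lacks LEU2, MET17 and URA3, and the arrays were checked against that. In the control arrays (n = 11) URA3 read 3.43 ± 0.245 (SD) and MET17 read 3.89 ± 0.215, near the low end of the signal range of 1.42 to 14. The 3 LEU2 probe sets read 5.47 to 5.68 on average, in the middle of the range, and reached 8.05 in a NaCl array. With NaCl (n = 3) they averaged 5.86 to 7.12, while URA3 read 4.17 ± 0.456 and MET17 read 4.14 ± 0.494. Signals of genes that the strain lacks were thus higher on average with NaCl than in the control arrays. The a-cell pheromone genes MFA1 (12.3 ± 0.402 and 8.49 ± 0.432 on its probe sets) and MFA2 (11.9 ± 0.284) were high. Of the genes of alpha cells, the receptor gene STE3 was low (3.75 ± 0.219) and the pheromone gene MF(ALPHA)1 was in the middle of the range (5.18 ± 0.308).

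Fold changes below are log2 values from limma with their standard error (SE), relative to control arrays of the same day unless other groups are named. Adjusted p values are limma's after Benjamini-Hochberg adjustment over 5171 genes, and they measure only the spread between these arrays, since the labels do not say that each array came from a separate culture. The genes with the largest changes were taken among those that moved the same way on every day. For each gene list, members that rose or fell are counted over all genes tested and again adjusted over the list alone. The test of a list is camera with a preset correlation between members, and its result with an estimated correlation is given beside it.

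Bleomycin (n = 3) raised HUG1, a small gene of the DNA damage checkpoint, by 4.65 ± 0.233 (25.2-fold, adjusted p = 9.51e-07). RNR3, which encodes a damage-induced large subunit of ribonucleotide reductase, rose by 2.15 ± 0.235 (adjusted p = 0.000396), and RNR2, its small subunit, by 2.09 ± 0.417 (adjusted p = 0.0241). The largest falls were in 7 genes, PIR1 by 3.92 ± 0.264 (adjusted p = 1.14e-05), DSE2 by 3.48 ± 0.247, EGT2 by 3.35 ± 0.23, DSE1 by 3.33 ± 0.313 and DSE4 by 2.93 ± 0.44. SUN4 and SCW11 fell by 2.67 ± 0.301 and 2.48 ± 0.189. NCA3, SPG1 and the hexose transporter gene HXT5 rose by 2.65 ± 0.278, 2.04 ± 0.217 and 1.99 ± 0.2, and the metallothionein gene CRS5 by 1.97 ± 0.208. CPP3 and YLR297W rose by 2.19 ± 0.239 and 1.96 ± 0.184. Of the stress genes, RTN2 rose by 1.73 ± 0.261, DDR2 by 1.66 ± 0.28, the small heat shock gene HSP26 by 1.97 ± 0.346 and the catalase gene CTT1 by 1.38 ± 0.293. RNR4 (1.4 ± 0.698, adjusted p = 0.549), DUN1 (1.06 ± 0.274, adjusted p = 0.0931), RAD54 (0.65 ± 0.186, adjusted p = 0.133) and HSP12 (2.00 ± 0.604, adjusted p = 0.164) were not called. MAG1, RAD2, DIN7, GPD1, HSP104, SSA4, ARN1, FIT2 and CLN2 were not called either, with adjusted p values from 0.0593 (CLN2) to 0.864 (RAD2).

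75 genes rose and 21 fell with bleomycin at an adjusted p under 0.05, and 532 had an unadjusted p under 0.05. Over all genes the median was -0.08. The count of 96 fell with any of its 6 arrays left out, to 63 without control replicate 2, 36 without control replicate 4, 42 without control replicate 5, 48 without bleomycin replicate 1, 38 without replicate 2 and 25 without replicate 3. HUG1 (highest adjusted p = 3.95e-05), RNR3 (0.0113) and RTN2 (0.0454) kept their call without any 1 of these arrays, as did PIR1, DSE1, DSE2, EGT2, SUN4, SCW11, NCA3, SPG1, HXT5, CRS5, CPP3 and YLR297W. RNR2 lost its call without control replicates 2, 4 or 5 or bleomycin replicates 2 or 3 (adjusted p up to 0.249), and DSE4 lost it without bleomycin replicate 3 (0.0786). DDR2 and HSP26 reached adjusted p values of 0.119 and CTT1 of 0.38. With the low-3′ arrays aside limma called 562 genes, each of the 96 among them. The class fit called 259 genes, 89 of them among the 96, and SUN4 was -1.39 there (adjusted p = 0.263).

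The DNA damage regulon rose as a list with bleomycin (median 0.74, adjusted p = 1.97e-11). Of its 16 members 4 rose and 12 were not called, and 7 rose adjusted over the list alone. Genes transcribed from G2/M to M/G1 fell (median -0.53, adjusted p = 1.33e-17), with 10 of 25 called lower and 12 adjusted over the list alone. The quiescence and stationary-phase markers rose (median 1.12, adjusted p = 8.68e-09), with 4 of 9 called and 6 adjusted over the list alone, SPG4 (2.25 ± 0.433) and SPG1 among them. SPG4 lost its call without each of the 6 arrays in turn (adjusted p up to 0.151). Osmotic stress genes (median 0.46, 3 of 22, 7 adjusted over the list alone), gluconeogenesis genes (median 0.39, 2 of 22, 5 adjusted over the list alone) and genes of protein degradation by ubiquitin and autophagy (median 0.52, 2 of 18, 3 adjusted over the list alone) rose. These 6 lists kept their call with an estimated correlation, with adjusted p values from 0.00734 for the damage regulon to 0.0121 for protein degradation.

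8 other lists were called with bleomycin at the preset correlation and lost the call with an estimated one. General stress genes rose (median 0.72, 7 of 29 called, 10 adjusted over the list alone, adjusted p = 2.33e-15) and had an adjusted p = 0.0682 with an estimated correlation. Trehalose and glycogen genes rose (median 0.52, 1 of 20, 2 adjusted over the list alone), with an adjusted p = 0.171 with an estimated correlation. Oxidative stress genes rose (median 0.19, 0 of 27, 1 adjusted over the list alone), with an adjusted p = 0.662 with an estimated correlation, and their call was lost without control replicate 2 (0.123) or bleomycin replicate 2 (0.157). Ribosome biogenesis genes fell (median -0.61, 0 of 58, 0 adjusted over the list alone), with an adjusted p = 0.556 with an estimated correlation. Ribosomal protein genes fell (median -0.39, 0 of 81, 0 adjusted over the list alone), with an adjusted p = 0.732 with an estimated correlation, and without control replicate 4 their adjusted p was 0.0555. Amino acid biosynthesis genes fell (median -0.53, 1 rose and 1 fell of 46, 1 and 3 adjusted over the list alone), with an adjusted p = 0.637 with an estimated correlation. HIS1 fell by 1.42 ± 0.227, and its call was lost without control replicate 4 or bleomycin replicates 2 or 3 (adjusted p up to 0.0786). Histone genes fell (median -1.03, 1 of 4, 1 adjusted over the list alone), with an adjusted p = 0.0522 with an estimated correlation. HTB2 fell by 2.21 ± 0.331, with an adjusted p = 0.335 in the fit without the day and 0.0786 without bleomycin replicate 3. Meiosis and sporulation markers rose (median 0.25, 0 of 10, 0 adjusted over the list alone), with an adjusted p = 0.662 with an estimated correlation, and turned to -0.08 without bleomycin replicate 1 (adjusted p = 0.814). The cell wall integrity list was not called (1 rose and 1 fell of 27, 3 and 2 adjusted over the list alone, adjusted p = 0.873), and its median of -0.07 was opposite in sign to the direction of the test.

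MMS (n = 3) raised the glutathione transferase gene GTT2 by 6.98 ± 0.416 (126-fold, adjusted p = 5.75e-07). The iron-sulfur scaffold genes ISU2 and ISU1 rose by 5.94 ± 0.485 and 5.06 ± 1.01, and the drug exporter genes ATR1 and FLR1 by 5.42 ± 0.243 and 5.06 ± 0.392. The ribonucleotide reductase genes RNR4 and RNR2 rose by 5.43 ± 0.735 and 3.87 ± 0.439, HUG1 by 2.87 ± 0.245, and RNR3 by 0.77 ± 0.247 (adjusted p = 0.0214). Of the repair genes, RAD23 of nucleotide excision repair rose by 4.17 ± 0.549, the alkyl-adenine glycosylase gene MAG1 by 1.96 ± 0.313 and the recombination gene RAD54 by 1.34 ± 0.196. The acid phosphatase gene PHO3 fell by 5.12 ± 0.519. Genes of small nucleolar RNAs, which guide the modification of ribosomal RNA, were among the largest falls. SNR56 was at -4.97 ± 0.628, SNR72 at -4.92 ± 0.674, SNR63 at -4.71 ± 0.301, SNR128 at -4.66 ± 0.369 and SNR75 at -4.52 ± 0.707. The arrays measured poly(A)+ RNA primed with oligo(dT), so whether these signals follow the mature small nucleolar RNAs was not tested. The checkpoint kinase gene DUN1 (-0.13 ± 0.289, adjusted p = 0.733), CTT1 (0.41, adjusted p = 0.292) and GPD1 (-0.19, adjusted p = 0.609) were not called.

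1731 genes rose and 879 fell with MMS, and 2926 had an unadjusted p under 0.05. Over all genes the median was 0.29, and 0.40 under median scaling. The count of 2610 ranged from 1885 without MMS replicate 2 to 2098 without control replicate 10. HSP104 (1.67 ± 0.462) lost its call without control replicate 11 or MMS replicate 2 (adjusted p up to 0.121), and RNR3 without control replicates 9 or 10 or MMS replicates 1 or 3 (up to 0.113). DIN7 and RAD2 rose by 0.91 and CLN2 fell by 0.58, and DIN7 lost its call without the arrays that RNR3 needed (up to 0.176) while RAD2 and CLN2 lost it without each of the 6 arrays in turn (up to 0.181 and 0.277). The 3 MMS arrays were higher than their same-day controls by 3.37 in the ACT1 5′ signal, and the class fit called 2080 genes, 1547 (59.3%) of the 2610 among them in the same direction and 8 in the opposite direction. Within the high class, which holds the 3 MMS arrays and none of their same-day controls, limma called 3646 genes, 2019 of the 2610 among them in the same direction and 88 in the opposite direction. GTT2 was 5.35, ISU2 4.45, ATR1 4.08, PHO3 -3.96, RAD23 2.43, MAG1 2.36, RNR2 2.19, RAD54 2.12 and HUG1 1.92 in the class fit. RNR4 was 2.09 there (adjusted p = 0.0761) and DUN1 was 0.77 (adjusted p = 0.0192). ENO2, which rose by 5.44 ± 1.17 in the day fit, was 0.31 there (adjusted p = 0.832), PGK1 (4.13) was 0.43 and SED1 (5.27) was 0.73 (adjusted p = 0.676 and 0.394). The class fit also drops the day, and these 3 genes had already lost their call without the day block, at 2.42, 1.87 and 2.77 (adjusted p = 0.168, 0.131 and 0.063).

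Each of the 37 proteasome genes rose with MMS (median 2.60, adjusted p = 7.45e-08), and 37 rose adjusted over the list alone, with PRE8 at 5.20 ± 0.528, RPT3 at 5.04 ± 0.669 and RPT5 at 4.32 ± 0.59. In the class fit 36 of them rose, with a median of 2.11, and the list had an adjusted p = 0.719 with an estimated correlation. Oxidative stress genes rose (median 3.09, 24 of 27, 25 adjusted over the list alone), with ZWF1 at 5.23 ± 0.536, PRX1 at 4.72 ± 0.442 and a class-fit median of 1.89. Their adjusted p was 5.29e-08, and adjusted p = 0.704 with an estimated correlation. Heat shock and chaperone genes rose (median 2.24, 24 of 27, 25 adjusted over the list alone), with AHA1 at 4.63 ± 0.485, STI1 at 4.47 ± 0.424, SSA4 at 3.76 ± 0.275 and a class-fit median of 1.71. Their adjusted p was 1.74e-06, and adjusted p = 0.719 with an estimated correlation. The DNA damage regulon rose (median 1.64, adjusted p = 0.00299), with 13 of 16 higher and 1 lower, the same numbers adjusted over the list alone, TFS1 at 5.16 ± 0.284 and a class-fit median of 1.73. It had an adjusted p = 0.559 with an estimated correlation. The 3 lists of repair genes were not called: in nucleotide excision repair 7 rose and 2 fell of 13 (adjusted p = 0.385), in homologous recombination 6 and 1 of 10 (adjusted p = 0.385) and in base excision and post-replication repair 6 and 2 of 17 (adjusted p = 0.482), with the same counts adjusted over the list alone. The class fit called nucleotide excision repair (6 rose and 0 fell, median 0.53, adjusted p = 0.0114) and not the others (adjusted p = 0.0854 and 0.516).

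Iron regulon genes rose with MMS (median 1.85, 22 higher and 2 lower of 29, 25 and 2 adjusted over the list alone), with TIS11 at 4.50 ± 0.247, ARN1 at 3.79 ± 0.295 and FIT2 at 3.07 ± 0.36. The list had an adjusted p = 0.000144, a class-fit median of 1.07 and an adjusted p = 0.716 with an estimated correlation. General stress genes rose (median 1.58, 17 of 29, 18 adjusted over the list alone, adjusted p = 0.0024), with HSP26 at 5.22 ± 0.365, GLK1 at 4.42 ± 0.571, HSP12 at 3.28 ± 0.636 and DDR2 at 2.84 ± 0.295. In the class fit 13 rose and 2 fell, and the list had an adjusted p = 0.719 with an estimated correlation. Protein degradation genes rose (11 of 18 higher and 1 lower, the same adjusted over the list alone), with APE1 at 4.66 ± 0.217, PEP4 at 4.17 ± 0.479 and UBI4 at 4.11 ± 0.437, and had an adjusted p = 0.693 with an estimated correlation. Sulfur genes rose (17 of 30, 17 adjusted over the list alone), with CYS3 at 3.89 ± 0.612 and MUP1 at 3.19 ± 0.412, and an adjusted p = 0.716 with an estimated correlation. Amino acid genes rose (median 1.20, 27 higher and 2 lower of 46, the same adjusted over the list alone), with ARG4 at 4.82 ± 0.604. They lost the call in the class fit (median 0.43, adjusted p = 0.16) and had an adjusted p = 0.822 with an estimated correlation.

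Of 58 ribosome biogenesis genes 14 fell and 4 rose with MMS (14 and 1 adjusted over the list alone; median -0.35, adjusted p = 0.0026), with NOP58 at -2.20 ± 0.314, BRX1 at -1.94 ± 0.384 and CBF5 at -1.76 ± 0.244. In the class fit 31 fell and none of the 58 rose, with a median of -1.06, and the list had an adjusted p = 0.822 with an estimated correlation. Of 81 ribosomal protein genes 22 fell and 12 rose (the same adjusted over the list alone; median -0.35, class-fit median -0.81), with RPS26B at -4.45 ± 0.41 and RPS22B at -3.38 ± 0.499, and they too had an adjusted p = 0.822 with an estimated correlation. G2/M to M/G1 genes fell (9 of 25, 9 adjusted over the list alone; median -0.35, class-fit median -1.03), with EGT2 at -2.07 ± 0.242 and DSE2 at -2.03 ± 0.261, and had an adjusted p = 0.704 with an estimated correlation. Of 52 small nucleolar RNA genes, a group formed after their values were seen, 49 fell with MMS (median -3.18), and 43 fell in the class fit (median -2.05). None of the 52 was called with bleomycin or cisplatin by limma. In the same group 6 rose and 16 fell with NaCl, and 2 rose and 1 fell with ethanol.

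Cisplatin (n = 2) raised the aryl-alcohol dehydrogenase gene AAD4 by 3.17 ± 0.31 (9-fold, adjusted p = 0.0017), the glutathione transferase gene ECM4 by 2.34 ± 0.269 and HUG1 by 2.30 ± 0.286 (both adjusted p = 0.00403). The oxidoreductase gene OYE3 rose by 2.01 ± 0.295, OSI1 by 1.82 ± 0.219, the drug exporter gene ATR1 by 1.69 ± 0.284 and RTA1 by 1.59 ± 0.257. The arginine synthesis genes ARG3 and ARG1 rose by 1.64 ± 0.23 and 1.56 ± 0.283, while the list of amino acid biosynthesis was not called (2 of 46 rose, 2 adjusted over the list alone, adjusted p = 0.849), and its median of -0.31 was opposite in sign to the direction of the test. PIR1, SUN4, EGT2 and SCW11 fell by 2.62 ± 0.324, 2.20 ± 0.37, 2.16 ± 0.282 and 1.44 ± 0.231. The purine gene ADE17 fell by 2.24 ± 0.3, ANB1 by 1.92 ± 0.361 and PLB2 by 1.57 ± 0.299. MAG1 (1.56 ± 0.365, adjusted p = 0.117), RNR2 (1.5 ± 0.512, 0.241), DUN1 (1.17 ± 0.337, 0.185), RAD54 (1.02 ± 0.228, 0.0979) and RNR3 (0.83 ± 0.288, 0.249) were not called, and neither were the other 13 preset genes beside HUG1, CLN2 (-1.08, 0.129) and HSP26 (1.25, 0.241) among them.

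17 genes rose and 7 fell with cisplatin, and 651 had an unadjusted p under 0.05. Under median scaling 18 rose and 19 fell. Without control replicate 1, cisplatin replicate 1 or cisplatin replicate 2, limma called 0 genes, so each named call rests on these arrays, and without control replicate 5 it called 14. Without 1 of those arrays the adjusted p of HUG1 reached 0.194, of AAD4 0.0772, of ECM4 0.171 and of PIR1 0.194. With the low-3′ arrays aside it called 1024, each of the 24 among them. The mean ACT1 5′ difference of -2.76 rests on the pair of cisplatin replicate 1 (-5.38). HUG1 kept its call in every setting with no array left out (adjusted p up to 0.0401), while PIR1, ADE17 and SUN4 lost their call in the class fit, which called 64 genes, 21 of them among the 24. SUN4 was -0.62 there (adjusted p = 0.883) and PIR1 was -1.51 (adjusted p = 0.285).

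The DNA damage regulon rose as a list with cisplatin (median 0.77, adjusted p = 5.53e-07), with 1 of 16 members called and 7 adjusted over the list alone, and it kept the call with an estimated correlation (adjusted p = 0.0395). G2/M to M/G1 genes fell (median -0.81, 3 of 25, 13 adjusted over the list alone), with an adjusted p = 0.0823 with an estimated correlation. Ribosome biogenesis genes fell (median -0.83, 0 of 58, 1 adjusted over the list alone), with an adjusted p = 0.704 with an estimated correlation. Oxidative stress genes rose (median 0.50, 2 of 27, 3 adjusted over the list alone), and protein degradation genes rose (median 0.40, 1 of 18, 3 adjusted over the list alone), with an adjusted p = 0.617 and 0.0778 with an estimated correlation. The quiescence markers rose (median 1.06, 0 of 9, 4 adjusted over the list alone), with an adjusted p = 0.0749 with an estimated correlation. Glycolysis genes fell (median -0.98, 0 of 17, 0 adjusted over the list alone), but their call was lost without control replicate 1 or cisplatin replicate 1 (median -0.60, adjusted p = 0.286), and in the class fit the median was 0.03 (adjusted p = 0.967). They had an adjusted p = 0.732 with an estimated correlation. 9 further lists were called at the preset correlation and lost with an estimated one, and 7 of these 9 also lost it with 1 array left out. General stress genes (median 0.47, 0 of 29, 0 adjusted over the list alone) lost it without control replicate 5 (0.095) or cisplatin replicate 2 (0.0831), the proteasome list without cisplatin replicate 2 (0.156), and the lists of checkpoint signalling, ergosterol, histones, gluconeogenesis and meiosis markers without control replicate 1 or cisplatin replicate 1 (adjusted p from 0.0708 to 0.286).

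With NaCl (n = 3) the plasma-membrane heat shock gene HSP30 fell by 5.87 ± 0.333 (58.4-fold, adjusted p = 4.03e-06), with day differences of -5.56, -5.83 and -6.20. The respiratory growth gene RGI1 fell by 5.09 ± 0.345, the hexose transporter genes HXT4, HXT7 and HXT6 by 5.08 ± 0.654, 4.09 ± 0.604 and 3.55 ± 0.515, and REE1 by 4.92 ± 0.522. Of the genes of glycogen and trehalose metabolism PGM2 fell by 4.95 ± 0.737, the glycogen phosphorylase gene GPH1 by 3.58 ± 0.347, the glycogen synthase gene GSY2 by 3.52 ± 0.449 and the trehalose synthase gene TSL1 by 2.0 ± 0.344. The mating genes PRM2 and FUS2 rose by 1.75 ± 0.227 and 1.28 ± 0.182. The largest rises were of small or poorly described genes, YLR285C-A at 3.20 ± 0.508, YDR524W-C at 3.11 ± 0.659 and YCR108C at 2.98 ± 0.575, together with HIS3 at 3.07 ± 0.653. Genes that the strain lacks also read higher on average with NaCl, such as URA3 at 4.17 against 3.43 in the control arrays. The rises were not tested apart from this. The glycerol synthesis gene GPD1 (0.18 ± 0.278, adjusted p = 0.593), a usual target of osmotic stress, was not called, nor was HUG1 (0.47 ± 0.237, adjusted p = 0.116).

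730 genes rose and 1943 fell with NaCl, and 3073 had an unadjusted p under 0.05. The median over all genes was -0.45. The 3 NaCl arrays differed from each other. Without NaCl replicate 1 the count was 3713, without replicate 2 it was 880, without replicate 3 it was 820, without control replicate 3 it was 811 and without control replicate 4 it was 1771, while without control replicate 2 it was 2687. Leaving aside the low-3′ arrays left NaCl replicate 1 alone, and the median over all genes was then -0.045 in place of -0.45. The spread in that fit comes from the other groups, and the lone array is assumed to vary like them, for the lists below as well. With only the NaCl arrays and their controls in the fit, limma called 1 gene, HSP30. HSP30, RGI1, REE1, PRM2, FUS2, HIS3 and the named genes of sugar transport and storage kept their call without any 1 array, as did YLR285C-A, YDR524W-C and YCR108C. RNR4 (-2.96 ± 0.712; days -0.07, -4.25 and -4.73), RNR2 (-1.78 ± 0.425), HSP12 (-2.23 ± 0.616; days 0.18, -2.99 and -3.75) and SNR52 (3.19 ± 0.837) lost it without control replicate 3, NaCl replicate 2 or NaCl replicate 3, with adjusted p values up to 0.0784, 0.0714, 0.121 and 0.0984. DUN1 (0.97), RAD2 (-0.97), CTT1 (-0.99) and DDR2 (-1.12) lost it without the same arrays (up to 0.127, 0.225, 0.154 and 0.0748), and DIN7 (0.98) and RNR3 (0.71) also without control replicate 4 (up to 0.169 and 0.182). The class fit called 1785 genes, 1444 of them among the 2673.

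General stress genes fell with NaCl (median -2.23, 26 lower and 1 higher of 29, 26 and 2 adjusted over the list alone, adjusted p = 1.2e-05), with HSP26 at -2.24 ± 0.353. With the low-3′ arrays aside the median was -1.16 and 15 fell, and the list had an adjusted p = 0.424 with an estimated correlation. Heat shock and chaperone genes fell (median -1.70, 22 of 27, 24 adjusted over the list alone), with HSP42 at -3.35, SSA1 at -3.33 ± 0.581 and HSP104 at -2.14 ± 0.447, and with the low-3′ arrays aside the median was -0.49 and 8 fell. They had an adjusted p = 0.706 with an estimated correlation. Glycolysis genes fell (median -3.20, 16 of 17, 16 adjusted over the list alone), with ENO2 at -5.79 ± 1.13, PGK1 at -4.54 ± 0.691 and ENO1 at -4.52 ± 0.725. With the low-3′ arrays aside the median was -0.87 and 3 fell, ENO2 was -2.01 in the class fit (adjusted p = 0.112), and the list had an adjusted p = 0.706 with an estimated correlation. Trehalose and glycogen genes fell (15 of 20, 15 adjusted over the list alone; median -1.5, and -1.71 without NaCl replicate 1, adjusted p = 0.0677), with an adjusted p = 0.424 with an estimated correlation.

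Respiration genes fell with NaCl (median -1.87, 36 of 40, 37 adjusted over the list alone, adjusted p = 1.4e-06), with ATP5 at -3.10 ± 0.585 and COX9 at -3.09 ± 0.523. With the low-3′ arrays aside the median was -0.59 and 9 fell, and the list had an adjusted p = 0.664 with an estimated correlation. Ribosomal protein genes fell (median -1.94, 64 lower and 2 higher of 81, 67 and 2 adjusted over the list alone), with RPL7A at -4.12 ± 0.797 and RPL3 at -3.83. With the low-3′ arrays aside the median was -0.31 and the call was lost (adjusted p = 0.0513), and the list had an adjusted p = 0.777 with an estimated correlation. Proteasome genes fell (median -1.43, 23 lower and 1 higher of 37, the same adjusted over the list alone, adjusted p = 0.0224), but with the low-3′ arrays aside the median was 0.25 and the list was called in the opposite direction (adjusted p = 0.0415, on 1 NaCl array). Their call was lost without control replicate 3 (0.103), NaCl replicate 2 (0.0997) or NaCl replicate 3 (0.103), and they had an adjusted p = 0.78 with an estimated correlation. Meiosis and sporulation markers rose (9 of 10, 9 adjusted over the list alone; median 1.49), with SPS2 at 1.87 ± 0.396 and SPO13 at 1.54 ± 0.284, and pheromone response genes rose (7 higher and 1 lower of 12, the same adjusted over the list alone; median 0.97). G1/S genes rose (11 higher and 3 lower of 30, the same adjusted over the list alone; median 0.18), with ASF1 at 2.05 ± 0.418, and without NaCl replicate 1 their adjusted p was 0.0677. These 3 lists each had an adjusted p = 0.424 with an estimated correlation. Their class-fit medians were 0.75, 0.91 and 0.20 in the order given. For the DNA-damaging agents against NaCl and ethanol, the meiosis list stood at -0.397, and at 0.0188 without the low-3′ arrays. Osmotic stress genes were not called as a list (3 rose and 9 fell of 22, 4 and 9 adjusted over the list alone, adjusted p = 0.957), and their median of -0.61 was opposite in sign to the direction of the test.

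With ethanol (n = 2) RGI1 fell by 5.35 ± 0.436 (adjusted p = 0.000232), HSP30 by 4.19 ± 0.422 and the ribosome-associated gene TMA10 by 3.88 ± 0.417. The ATP synthase regulator gene STF2 fell by 3.35 ± 0.43 and the protein-sorting gene BTN2 by 2.97 ± 0.555. The thiamine transporter gene THI7 rose by 3.51 ± 0.314 (11.4-fold, adjusted p = 0.000305), the aspartate aminotransferase gene AAT1 by 3.45 ± 0.463, the ester synthesis gene EEB1 by 3.03 ± 0.442 and YMR209C by 3.01 ± 0.278. Of the genes of mating FUS1 rose by 2.66 ± 0.318, AGA2 by 2.22 ± 0.284, KAR4 by 2.10 ± 0.49 and AGA1 by 1.97 ± 0.333. Of the genes that build ribosomes NOC2 rose by 3.16 ± 0.716, DBP7 by 2.87 ± 0.64 and PWP2 by 2.81 ± 0.486. Of amino acid genes ARG3 rose by 1.96 ± 0.241, SER3 by 2.10 ± 0.496 and ASN1 by 2.33 ± 0.557. Of the genes of carbohydrate stores TSL1 fell by 2.48 ± 0.435, GLC3 by 2.05 ± 0.372 and GSY1 by 2.05 ± 0.371. RAD54 rose by 1.01 ± 0.24 (adjusted p = 0.0353) but was 0.50 in the class fit (adjusted p = 0.293). HUG1 (-0.24, adjusted p = 0.656), RNR2 (0.04) and HSP12 (-0.45, adjusted p = 0.762) were not called, nor was any other preset gene beside RAD54, with SSA4 lowest in adjusted p (-1.21, 0.0622).

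198 genes rose and 61 fell with ethanol, and 1228 had an unadjusted p under 0.05. Over all genes tested it was 0.14 in the median. Without control replicate 6 the count was 79, without control replicate 7 it was 6, without ethanol replicate 1 it was 81 and without ethanol replicate 2 it was 6. RGI1, HSP30, THI7, YMR209C and ARG3 kept their call without any 1 of these arrays (adjusted p up to 0.0486). AAT1, TMA10, STF2, FUS1 and AGA2 lost it without control replicate 7 or ethanol replicate 2, with adjusted p values up to 0.095, 0.0653, 0.116, 0.0867 and 0.107, and the other named genes lost it there too. The class fit called 603 genes, 204 of them among the 259. With the low-3′ arrays aside limma called 2202, each of the 259 among them.

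Ribosome biogenesis genes rose as a list with ethanol (median 1.20, 9 of 58, 17 higher and 1 lower adjusted over the list alone, adjusted p = 6.99e-07), with an adjusted p = 0.977 with an estimated correlation. General stress genes fell (median -0.95, 3 of 29, 4 adjusted over the list alone), as did trehalose and glycogen genes (median -0.75, 5 of 20, 7 lower and 1 higher adjusted over the list alone), both with an adjusted p = 0.85 with an estimated correlation. Heat shock and chaperone genes fell (median -0.41, 4 of 27, 5 adjusted over the list alone), with HSP78 at -1.48 ± 0.325, and amino acid genes rose (median 0.51, 5 of 46, 7 adjusted over the list alone). Both had an adjusted p = 0.977 with an estimated correlation. Hexose transporter genes fell (median -0.68, 0 of 16, 6 adjusted over the list alone), with an adjusted p = 0.232 with an estimated correlation. Pheromone response genes rose (median 0.51, 3 of 12, 4 adjusted over the list alone, adjusted p = 0.0415), and without control replicate 7 or ethanol replicate 2 the adjusted p was 0.146 and 0.145. The a-cell markers rose (median 0.97, 1 of 7, 1 adjusted over the list alone, adjusted p = 0.0484), and this call was lost without control replicate 6 (0.0989), control replicate 7 (0.076), ethanol replicate 1 (0.0974) or ethanol replicate 2 (0.0752). These lists had an adjusted p = 0.85 and 0.977 with an estimated correlation.

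**Figure D2:**
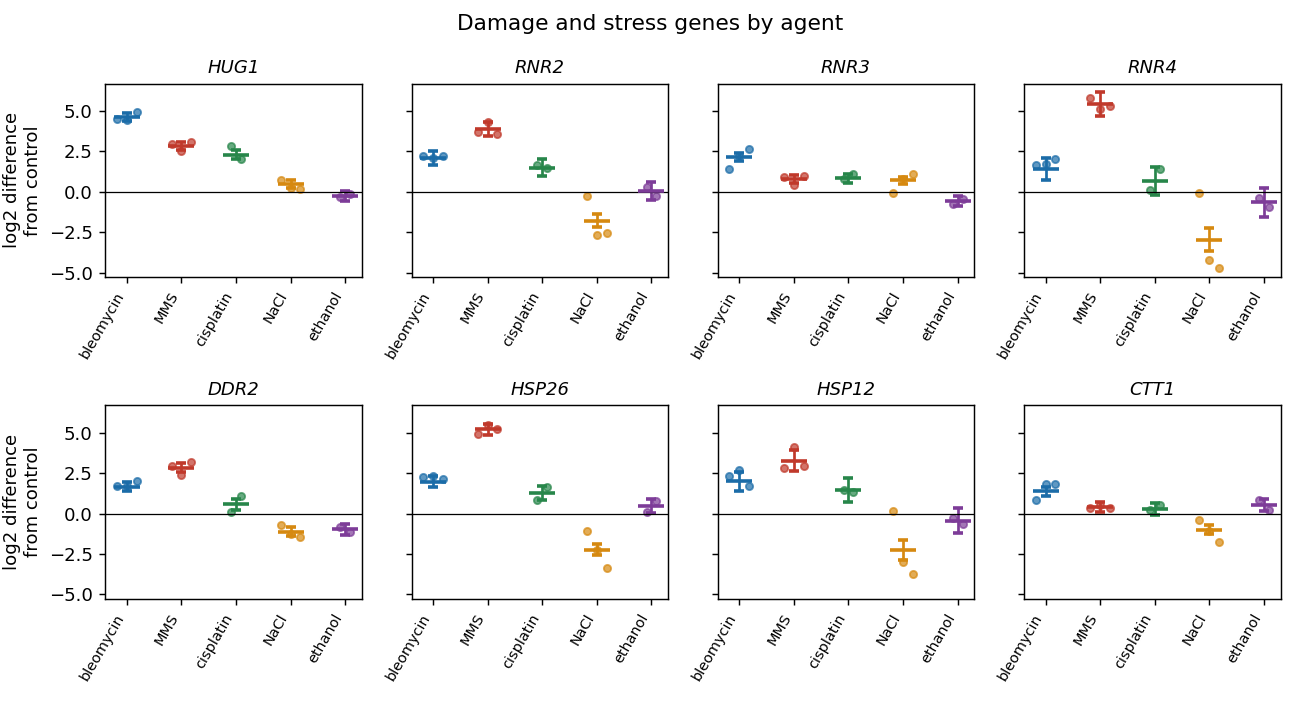
Log2 fold change against control of 8 genes for each agent (vertical axis; dashes, limma's fitted value with its SE; points, the difference of a treated array from its same-day control). HUG1 rose with bleomycin (4.65), MMS (2.87) and cisplatin (2.30), and HSP26 rose with MMS (5.22) and fell with NaCl (-2.24).

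**Figure D3:**
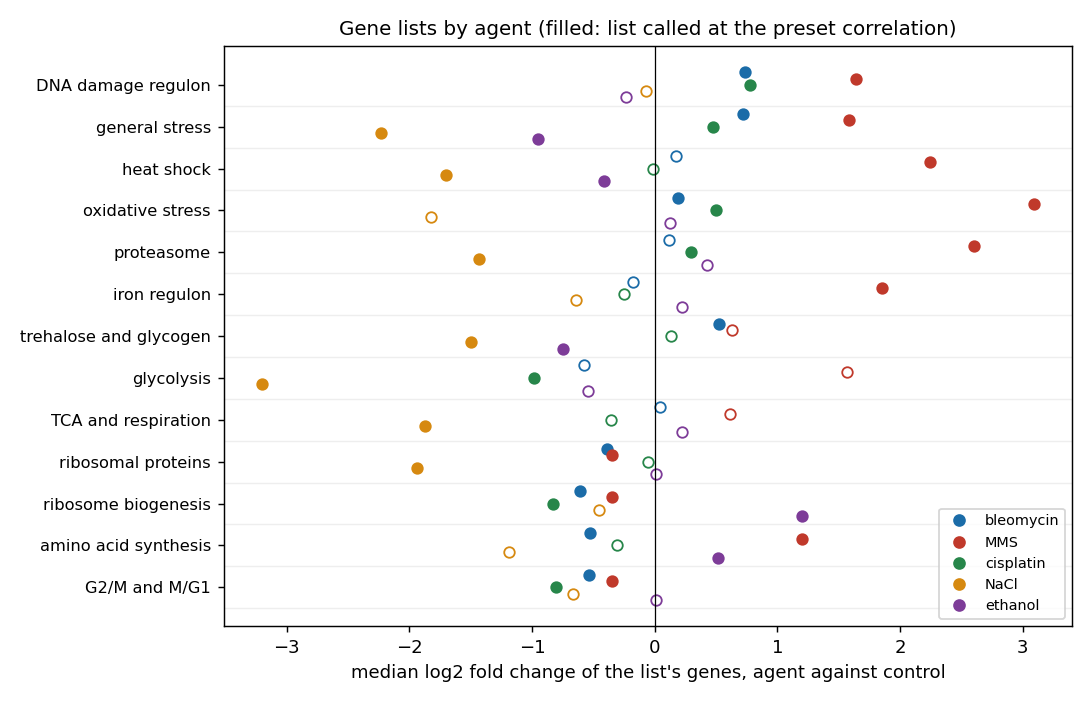
Median log2 fold change of 13 gene lists (horizontal axis) by agent, with filled points where camera called the list at the preset correlation. Ribosome biogenesis genes sit at -0.61 with bleomycin and at 1.20 with ethanol.

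9 genes rose and 2 fell with each of bleomycin, MMS and cisplatin. HUG1 rose by 4.65 ± 0.233, 2.87 ± 0.245 and 2.30 ± 0.286 in that order, ECM4 by 1.83 ± 0.219, 3.28 ± 0.231 and 2.34 ± 0.269, and YLR297W by 1.96 ± 0.184, 2.63 ± 0.194 and 1.53 ± 0.226. GSP2, a gene of nuclear transport, rose by 1.86 ± 0.287, 2.96 ± 0.302 and 2.18 ± 0.352, and HXT5 by 1.99 ± 0.2, 1.28 ± 0.21 and 1.46 ± 0.245. CPP3, the phospholipase gene CLD1, APE1 and ARG3 rose too, and EGT2 and SCW11 fell. ARG3 also rose with NaCl (0.81, adjusted p = 0.00678) and ethanol (1.96), EGT2 (-2.49, adjusted p = 0.000117) and SCW11 (-1.14, adjusted p = 0.00177) also fell with NaCl, and APE1 rose with ethanol (1.02, adjusted p = 0.0485), a call lost without each of the 4 arrays in turn (up to 0.371). YLR297W fell with NaCl (-1.15, adjusted p = 0.00149), as did ECM4 (-0.67, adjusted p = 0.0263), whose call was lost without each array but NaCl replicate 1 (up to 0.143). APE1 fell with NaCl (-0.54, adjusted p = 0.0478), a call lost without each array but NaCl replicate 1 (up to 0.158) and opposite in sign in the class fit (0.25). With bleomycin APE1 lost its call without each of the 6 arrays in turn (adjusted p up to 0.451), GSP2 without bleomycin replicates 2 or 3 (0.0786) and CLD1 without control replicates 2 or 4 or bleomycin replicates 1 or 2 (up to 0.111). ARG3 lost it there without each array but bleomycin replicate 1 (up to 0.266), and CPP3 lost it with MMS without control replicates 9 or 10 or MMS replicates 1 or 3 (up to 0.106). In the cisplatin comparison each of the 11 calls was lost without control replicate 1 or without either cisplatin array, where limma called 0 genes.

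The effects of the 3 DNA-damaging agents, averaged, were compared with the average of NaCl and ethanol to find genes that respond to DNA damage rather than to stress. A difference of these averages can rest on a single agent. HSP30 was higher by 5.87 ± 0.324 (adjusted p = 2.93e-06), RGI1 by 4.85 ± 0.336, PGM2 by 4.57 ± 0.717, RNR4 by 4.30 ± 0.693 and TMA10 by 4.20 ± 0.321. All 5 had fallen with NaCl, RNR4 by 2.96 (a call lost without control replicate 3 or NaCl replicates 2 or 3, adjusted p up to 0.0784) and TMA10 by 2.91, and HSP30, RGI1 and TMA10 had also fallen with ethanol. RNR4 had not been called with bleomycin or cisplatin. HUG1 was higher by 3.16 (adjusted p = 1.38e-05), YLR297W by 2.75, ECM4 by 2.67, GSP2 by 2.28 and HXT5 by 2.06, while ARG3 did not differ (0.18, adjusted p = 0.505). The spliceosomal RNA gene SNR14 was lower (-2.91 ± 0.318), as were PHO3 (-2.56 ± 0.49) and the ribosome assembly gene UTP20 (-2.50 ± 0.326). These genes kept their call without any 1 array. PHO3 had fallen with MMS, and it was lower with MMS than with bleomycin. The glycolysis gene ENO2 was higher by 4.56 ± 1.1 (adjusted p = 0.0114), and its call was lost without control replicate 7 or ethanol replicate 2 (0.0773).

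916 genes were higher and 380 lower in this comparison, and 1945 had an unadjusted p under 0.05. The median over all genes was 0.17. Without control replicate 6 the count was 738, without control replicate 7 it was 655, without ethanol replicate 1 it was 735, without ethanol replicate 2 it was 659, without cisplatin replicate 2 it was 821 and without NaCl replicate 1 it was 2746. The class fit called 1376 genes, 1005 of them among the 1296. The damage regulon was higher (median 1.03, 7 of 16, 8 adjusted over the list alone, adjusted p = 0.000108), with an adjusted p = 0.0926 with an estimated correlation. General stress genes were higher (median 2.45, 28 of 29, 28 adjusted over the list alone), as were heat shock genes (median 2.07, 21 of 27, 24 adjusted over the list alone) and oxidative stress genes (median 1.94, 20 of 27, 23 adjusted over the list alone). They had an adjusted p = 0.14, 0.294 and 0.198 with an estimated correlation, and none of the 35 lists kept a call there (lowest 0.0926). Proteasome genes were higher (median 1.48, 22 of 37, 32 adjusted over the list alone) and ribosome biogenesis genes lower (median -1.03, 24 of 58, 29 adjusted over the list alone), with an adjusted p = 0.504 and 0.346 with an estimated correlation. Against control, the proteasome median was 0.12 with bleomycin, 2.60 with MMS, 0.30 with cisplatin, -1.43 with NaCl and 0.43 with ethanol. The heat shock median was 0.17, 2.24, -0.02, -1.70 and -0.41 in that order. For these 2 lists the averages therefore rest largely on MMS and NaCl and do not show a rise with each damaging agent.

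MMS and bleomycin were compared to ask whether the response depends on the kind of damage. ISU2 was higher with MMS by 6.79 ± 0.669 (adjusted p = 6.47e-05), GTT2 by 6.09 ± 0.573, ATR1 by 5.80 ± 0.335 and YNL208W by 5.74 ± 0.78. SNR72 (-5.47 ± 0.929), PHO3 (-5.37 ± 0.717) and SNR56 (-4.71 ± 0.866) were lower, and these calls held without any 1 array. ENO2 (6.54 ± 1.61) and SED1 (6.19 ± 1.21) were higher, but were -0.36 and 0.24 in the class fit (adjusted p = 0.867 and 0.863). 1337 genes were higher with MMS and 538 lower (2472 at an unadjusted p under 0.05). The median over all genes was 0.40, and 0.55 under median scaling. The oxidative stress list (median 2.93, 19 of 27, 19 adjusted over the list alone) and the proteasome list (median 2.62, 24 of 37, 37 adjusted over the list alone) were higher, both with an adjusted p = 0.912 with an estimated correlation. The class fit called 1428 genes, 904 of them among the 1875.

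Cisplatin differed from bleomycin in 7 genes, 5 higher and 2 lower (247 at an unadjusted p under 0.05), and under median scaling 2 were higher and 2 lower. HUG1 (-2.35 ± 0.324, adjusted p = 0.0286) and the dehydrogenase gene BDH2 (-2.05 ± 0.322) were lower with cisplatin. DSE2 was higher by 2.47 ± 0.344, AAD4 by 2.38 ± 0.352, ATR1 by 2.06 ± 0.321, the aromatic amino acid gene ARO10 by 2.04 ± 0.293 and ARG1 by 2.01 ± 0.321. limma called 0 genes without control replicates 1, 4 or 5 or any 1 of the 5 treated arrays, and 2 without control replicate 2. Amino acid genes were higher (median 0.41, adjusted p = 1.96e-05) and general stress genes lower (median -0.59), with an adjusted p = 0.744 and 0.646 with an estimated correlation.

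Against MMS, cisplatin gave higher SNR72 (6.72 ± 1.04), DYN2 (5.20 ± 0.389, adjusted p = 3.12e-05) and RPS26B (5.13 ± 0.629), and lower ISU2 (-6.45 ± 0.745, adjusted p = 0.000167) and LSB5 (-6.17 ± 0.906). ENO2 was lower at -7.81 ± 1.79, but stood at -0.27 in the class fit (adjusted p = 0.93), and its call was lost without control replicate 1 or cisplatin replicate 1 (0.0702). 539 genes were higher and 1326 lower (2435 at an unadjusted p under 0.05). The median over all genes was -0.43, and -0.59 under median scaling. The count was 856 without control replicate 1, 853 without cisplatin replicate 1 and 985 without cisplatin replicate 2, and the class fit called 1004 genes, 685 of them among the 1865. Oxidative stress genes were lower (median -2.44, 18 of 27, 19 adjusted over the list alone), and none of the 35 lists kept a call with an estimated correlation (lowest adjusted p = 0.958).

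Ethanol differed from NaCl in 1863 genes, 1357 higher and 506 lower (2714 at an unadjusted p under 0.05). The serine hydroxymethyltransferase gene SHM2 was higher by 5.52 ± 0.92 (adjusted p = 0.0084), the mitochondrial genes RIM1 and COX9 by 5.26 ± 1.17 and 4.92 ± 0.843, and YDR034C-A was lower at -5.85 ± 1.13 (adjusted p = 0.0133). The median over all genes was 0.70, and 0.82 under median scaling. limma called 0 genes without control replicate 7 or ethanol replicate 2, 124 without control replicate 6 or ethanol replicate 1, 331 without control replicate 3, 333 without NaCl replicate 3, 219 without NaCl replicate 2, 1041 without control replicate 4 and 3610 without NaCl replicate 1. Respiration genes were higher (median 1.94, 23 of 40, 27 adjusted over the list alone) and meiosis markers lower (median -1.81, 7 of 10, 8 adjusted over the list alone), and none of the 35 lists kept a call with an estimated correlation (lowest adjusted p = 0.929).

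Bleomycin and cisplatin, which share 1 control array, both raised 9 genes and lowered 5, with none in opposite directions. Independent lists of these sizes would share 0.247 and 0.0284 genes. Unchanged groups simulated with the same controls shared 0, which decides nothing, since groups without effects give few calls to share. The fold changes of bleomycin and cisplatin correlated across genes at 0.662 (simulated 0.233), with a covariance of 0.173 (simulated 0.0369), and genes are not independent replicates. In the class fit this correlation was 0.668 (simulated 0.186). Part of the excess may come from the shared control, since the controls could not be split with at least 2 arrays in each part. Bleomycin and NaCl, which share 2 control arrays, correlated at 0.332 (simulated 0.357), with a covariance of 0.176 (simulated 0.047). In the class fit their correlation was -0.101 (simulated 0.143). They both raised 9 genes (10.6 for independent lists) and lowered 16 (7.89), with 31 in opposite directions, and part of any excess may come from the shared controls. Cisplatin and NaCl, which share none, correlated at 0.385 (simulated 0.0855), with a covariance of 0.245 (simulated 0.0138). In the class fit that correlation was -0.0963 (simulated 0.162). MMS and cisplatin, which also share none, both raised 16 genes (5.69 for independent lists) and lowered 4 (1.19). MMS and bleomycin both raised 43 genes (25.1) and lowered 8 (3.57), with 13 in opposite directions. MMS and NaCl both raised 100 genes (244 for independent lists) and lowered 189 (330), while 1040 moved in opposite directions and the correlation was -0.338. In the class fit, where all agents share the controls, the correlation was 0.14 for MMS and NaCl (simulated 0.0522), 0.43 for MMS and bleomycin (simulated 0.256, and 0.0341 in the day fit) and 0.538 for MMS and cisplatin (simulated 0.179, and -0.158 in the day fit). Part of these values may come from the shared controls.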

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

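The whole-cause tests for MMS and for its fall in small nucleolar RNAs were chosen only after the results were seen, and so were the ACT1 5′ classes they use.

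Control probe sets stood more than 1 log2 unit above the highest control array on 3 arrays. On bleomycin replicate 3 the 18S ribosomal RNA probe set 18srRnaa_at read 8.22 (3.64 to 5.96 in the control arrays) and the 25S probe set 25srRnae_at read 11.1 (5.97 to 7.37). On NaCl replicates 2 and 3 the opposite-strand spike probe set BioB-3_st read 7.84 and 7.74 (5.18 to 6.62). BioB-M_st read 6.55 on NaCl replicate 2 (3.95 to 5.49) and BioC-3_st read 6.45 on NaCl replicate 3 (3.69 to 5.38). The report's comparisons use none of these probe sets. The gap test used for single arrays runs on groups of 4 to 10, and no group has that size. Among the 11 control arrays, replicate 11 had a median correlation of 0.809 with the others, which lay at 0.903 or higher, and this gap was not tested.

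The MMS calls were weighed against the ACT1 5′ signal, which was 3.37 higher in the MMS arrays than in their same-day controls. As the whole cause it is argued against for the 59.3% of the 2610 calls that kept their direction and their call in the class fit. The class does not equalize the 5′ signal. Within the high class the MMS arrays read 8.35 to 8.83, below the control arrays at 9.46 to 10.65. The class fit also drops the day, and differences in RNA state that the 5′ signal does not follow were not tested. As a part of the cause it stays open, as does an effect of MMS itself, since the MMS fold changes correlated across genes at 0.62 with the difference between 5 high-class and 3 low-class control arrays of other days. Some of the 2610 calls may therefore come from the RNA state of the same-day controls. The class fit gave a correlation of 0.0785, which decides nothing, since that fit removes the class difference by construction.

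The NaCl calls were weighed against a state shared with control replicate 11, the control array of low ACT1 3′ signal. The mean change of NaCl replicates 2 and 3 correlated across genes at 0.745 with the difference of that control array from 5 other low-class controls, so a shared RNA state may be part of the cause. For NaCl replicate 1 the correlation was 0.0381, and its change correlated at 0.302 with that of the other 2. Whether the state of NaCl replicates 2 and 3 is the whole cause stays open, since 65.7% of the 3713 calls made without replicate 1 (2439) had the same sign in replicate 1, which a shared sign by chance and a true effect of salt could both give. The 10%, 8% and 9% doses were not tested apart from that state.

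The fall of small nucleolar RNA genes with MMS was weighed as the third pattern. Quantile normalization is argued against, since their median was -3.17 under median scaling and -3.18 in the report. The ACT1 5′ signal may be part of the cause, since these genes were lower in the high-class controls of other days by a median of -0.726 (quartiles -1.03 to -0.0322, 39 of 52 lower). It is argued against as the whole cause, since 43 of the 52 genes still fell in the class fit, with the limits of that fit given above. A biological fall with MMS stays open and was not tested further. Since poly(A)+ RNA primed with oligo(dT) was measured, the signals may not follow the mature small nucleolar RNAs, which was not tested either.

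Other splits of the arrays were counted for comparisons of at least 3 arrays per group. Swapping treated and control arrays within days gives 4 splits for an agent, too few for a share under 0.05. The real value was 96 genes for bleomycin, 2610 for MMS and 2673 for NaCl, the highest other split gave 0 for each by limma (532, 2926 and 3073 at an unadjusted p under 0.05 in the real split), and only the real one of each set reached its own value, 1 of 4. Splits of 14 arrays in a fit without the day excluded a random draw of arrays for that fit alone, since 1 of 100 reached the real value for bleomycin (188, highest other 1), MMS (2457, highest other 994, with control replicates 6, 9 and 11 as the treated group) and NaCl (1344, highest other 1061, with control replicates 6 and 11 and NaCl replicate 3). These splits ignore the pairing by day, and the 994 and 1061 genes show that the arrays differ by more than their treatment, so chance is not excluded for the fit with the day. For the DNA-damaging agents against NaCl and ethanol, the splits kept the day as a block but joined the agents of each side into 1 group, which gave a real count of 522 (1296 in the report, with each agent as its own group). 2 of 100 splits, the real one included, reached 522, which excludes a random draw of single arrays for that fit. It does not exclude a draw of whole agents, since arrays of an agent may move together and the splits part them. The highest other, with 1194 genes, put bleomycin replicate 1, ethanol replicate 2 and the 3 NaCl arrays on 1 side, and so shares 4 of 5 arrays with the real one. Both sets of 5 arrays are of the low ACT1 5′ class, and whether the class drives the count was not tested with these splits. With the class as the block in place of the day, limma called 1376 genes for this comparison. MMS against bleomycin has only 10 splits, too few for a share under 0.05, and its real value was 1875 against a highest other of 0 by limma (2472 at an unadjusted p under 0.05 in the real split).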

How the results depend on the processing

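The fits by ACT1 5′ class and those leaving aside the 3 arrays of low ACT1 3′ signal were chosen only after the results were seen.

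Of 323 pairs of a named gene and a comparison, 265 were called. Median scaling kept 256 of these calls, a pseudocount 262, no filter 263, eBayes without a trend 261 and all probe sets that are not controls 243, and none of them reversed a gene. The stricter filter tested 239 of the calls and kept each. The fit with only the arrays compared kept 182, the class fit 231 and the fit without the low-3′ arrays 231. Within the low ACT1 5′ class 43 of 161 were kept and within the high class 145 of 152. Of 108 called lists 102 kept their call under median scaling, 98 without a filter, 89 in the class fit and 7 with an estimated correlation. Why the estimated correlation ended most of these calls was not tested. Lists were not run under the random block, since camera takes none.

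The pairing by day moved many calls. With no replicate block limma called 2408 genes for DNA-damaging agents versus NaCl and ethanol, 1229 for MMS versus bleomycin, 210 for bleomycin versus control, 954 for cisplatin versus MMS and 603 for ethanol versus control, and shared calls between agents came to 759. With day as a random block these were 2375, 208 (bleomycin versus control), 1003 (cisplatin versus MMS) and 600 (ethanol versus control). With no block 225 of the 265 calls were kept. With the ethanol array of another year as its own day, the counts were 735 for DNA-damaging agents versus NaCl and ethanol, 0 for cisplatin versus bleomycin by limma (247 at an unadjusted p under 0.05 in the report's fit), 124 for ethanol versus NaCl and 79 for ethanol versus control. That setting leaves 1 ethanol array without a control of its day. Otherwise the cause was not tested.

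Under median scaling bleomycin versus control came to 146 genes, cisplatin versus bleomycin to 4 and cisplatin versus control to 37, and the cause was not tested. All probe sets that are not controls gave 4396 for NaCl versus control, 15 for cisplatin versus control and 3197 for ethanol versus NaCl, over more tests. A minimum of 2-fold left 244 shared calls between agents. With only the arrays of the agents compared, NaCl versus control fell to 1 gene, bleomycin versus control came to 514, cisplatin versus bleomycin to 34, cisplatin versus control to 10, ethanol versus NaCl to 0 (2714 at an unadjusted p under 0.05 in the report's fit) and ethanol versus control to 1352. These fits hold fewer arrays and estimate the spread from them alone.

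In the class fit bleomycin versus control came to 259 genes, cisplatin versus MMS to 1004, cisplatin versus bleomycin to 15, cisplatin versus control to 64 and ethanol versus control to 603. DUN1, MMS versus control, turned to 0.77 (adjusted p = 0.0192), ENO1, cisplatin versus MMS, to 0.44, ENO2, MMS versus bleomycin, to -0.36 and APE1, NaCl versus control, to 0.25. Within the high ACT1 5′ class DUN1 was 0.81 and ENO1 was 0.25, and the counts were 3076 for MMS versus bleomycin, 1014 for bleomycin versus control, 101 for cisplatin versus bleomycin and 822 for cisplatin versus control. Within the low class the counts were 399 for NaCl versus control, 7 for bleomycin versus control, 0 for cisplatin versus bleomycin (247 at an unadjusted p under 0.05 by limma in the report's fit), 1 for cisplatin versus control, 98 for ethanol versus NaCl and 58 for ethanol versus control. SUN4, cisplatin versus control, was 0.40 on 1 cisplatin array (adjusted p = 1) and APE1, NaCl versus control, 0.29 (adjusted p = 0.548) there, so neither was called. The high class holds 2 bleomycin arrays and 1 cisplatin array and the low class 1 of each, so each count with cisplatin, and each count with bleomycin in the low class, rests on an arm of 1 array. A lone array is assumed to vary like the other groups, which give the spread. The cause was not tested beyond that.

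Leaving aside the low-3′ arrays gave 2348 genes for DNA-damaging agents versus NaCl and ethanol, 867 for NaCl versus control, 562 for bleomycin versus control, 2918 for cisplatin versus MMS, 98 for cisplatin versus bleomycin, 1024 for cisplatin versus control, 789 for ethanol versus NaCl and 2202 for ethanol versus control. With NaCl versus control, HSP12 turned to 0.14, RAD2 to 0.020 and MAG1 to -0.92 (adjusted p = 0.0369), and the list of proteasome, NaCl versus control, to 0.25 (adjusted p = 0.0415, a call in the opposite direction). That setting leaves a single NaCl array, assumed to vary like the other groups, and the cause was not tested otherwise.

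Lists reversed where the direction of their test turned, which can differ from the sign of the median. The list of glycolysis and fermentation, cisplatin versus control, stood at 0.114 with no replicate block, 0.0333 in the class fit and 0.412 in the low class. The list of glycolysis and fermentation, cisplatin versus MMS, stood at -0.527, at 0.361 and, in the high class, at -0.0282. The list of cell wall integrity, cisplatin versus control, stood at 0.0456 with no replicate block and 0.289 in the low class, and that list, cisplatin versus MMS, at -0.172, at 0.152 in the class fit and at -0.176 in the high class. The list of markers: meiosis and sporulation markers, bleomycin versus control, stood at -0.192 with no replicate block, -0.0754 in the class fit and -0.276 in the low class, and at -0.083 to 0.498 with 1 array left out. For MMS versus bleomycin it stood at 0.182 in the class fit and 0.124 in the high class, for cisplatin versus MMS at -0.0812, for cisplatin versus control at -0.0247 in the low class, and for DNA-damaging agents versus NaCl and ethanol at 0.0188 without the low-3′ arrays. In the low class the list of cytosolic ribosomal proteins, bleomycin versus control, stood at 0.294 and the list of ergosterol, cisplatin versus control, at 0.205. The cause was not tested.

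With 1 array left out, limma called 25 to 63 genes for bleomycin versus control, 0 to 14 for cisplatin versus control (651 at an unadjusted p under 0.05 in the report's fit), 811 to 3713 for NaCl versus control and 6 to 81 for ethanol versus control. The ranges were 655 to 2746 for DNA-damaging agents versus NaCl and ethanol, 853 to 1651 for cisplatin versus MMS, 0 to 2 for cisplatin versus bleomycin and 0 to 3610 for ethanol versus NaCl. Where a group of 2 keeps 1 array, that array is assumed to vary like the others. MMS versus control stayed within 1885 to 2098. Of the lists called at the preset correlation, 3 of 14 lost the call without some array for bleomycin versus control, 0 of 12 for MMS, 8 of 16 for cisplatin, 3 of 10 for NaCl and 2 of 8 for ethanol. For DNA-damaging agents versus NaCl and ethanol 5 of 20 lost it, for MMS versus bleomycin 2 of 7, for cisplatin versus bleomycin 5 of 9, for cisplatin versus MMS 5 of 9 and for ethanol versus NaCl 0 of 3. Where a day holds 1 treated and 1 control array, leaving out either one also takes the other out of the fit with day as a block.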

Other observations

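The values in this part were picked out after they were seen, and no further test was run on them.

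The iron regulon was called as a list with MMS, with 22 higher and 2 lower of 29 (adjusted p = 0.000144), and lost the call with an estimated correlation (adjusted p = 0.716). ISU1 and ISU2, the scaffolds on which iron-sulfur clusters are built, rose by 5.06 ± 1.01 and 5.94 ± 0.485 (SE, n = 3), and ISU2 was 4.45 in limma's class fit. The siderophore transporter gene ARN1 rose by 3.79 ± 0.295 and the mannoprotein gene FIT2 by 3.07 ± 0.36. With NaCl (n = 3) FIT2 fell by 1.98 ± 0.348 and ARN1 by 0.86, and the call of ARN1 was lost without control replicates 3 or 4 or NaCl replicates 2 or 3 (adjusted p up to 0.181). TIS11, which promotes the decay of messengers when iron is scarce, rose by 4.50 ± 0.247 with MMS.

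Pheromone response genes were called as a list with NaCl (median 0.97) and with ethanol (median 0.51) at camera's preset correlation, and lost the call with an estimated one (adjusted p = 0.424 and 0.85). With MMS their median was 0.74, with 4 higher and 1 lower of 12, and the list was not called (adjusted p = 0.385). With NaCl PRM2 rose by 1.75 ± 0.227 and FUS2 by 1.28 ± 0.182 (n = 3). With ethanol FUS1 rose by 2.66 ± 0.318 and AGA2 by 2.22 ± 0.284 (n = 2), calls that were lost without control replicate 7 or ethanol replicate 2 (adjusted p up to 0.0867 and 0.107). In the comparison of the DNA-damaging agents with NaCl and ethanol, 4 of 12 pheromone response genes were lower (median -0.63, adjusted p = 0.000122 with camera's preset correlation and 0.14 with an estimated one).

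The spike-in controls, bacterial RNAs with probe sets of their own, also differed between groups. Their mean signal was 10.3 ± 0.208 (SD, n = 3) with NaCl, 8.9 ± 0.752 in the control arrays (n = 11) and 7.79 ± 0.483 with MMS (n = 3). The labels do not say how much spike-in or cRNA went on each array, so this difference was not tested further.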
